A study of Mus musculus with 56 samples.

How the data were processed

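RNA from 56 samples was extracted with Trizol and a column kit, labelled with biotin and hybridised to Affymetrix whole-transcript arrays, per the labels. The labels give one labelling protocol for GTML tumours and P7 cerebella and a different one for the transplanted tumours and the cultured cells of their series; which of them was used for the GTML tumour cells is not clear from the labels. The deposited values are log2 levels that the authors made with RMA, and the submitters' processing notes name the mouse build mm9. The version and settings of RMA, and whether all 56 arrays were processed together, are not given in the sources used here. There were 17831 probes, with values from 2.37 to 14.88, and array medians ran from 7.86 to 8.26. Blank cells made up 3.12% of all cells (31111 cells, in 2771 probes), and 99.2% of them belonged to probes in the dimmer part of it. The rule that blanked them is not given in the sources used here, so they were left missing, and a setting chosen after seeing the data filled them with the percentile 1 value of the array. Probes were joined to genes by the probe annotation supplied with the series: 15620 carried a single gene symbol and were kept, 1370 carried several and 841 none. Of the 15224 genes, 375 had several probes and were represented by the probe with the highest mean. No positions are given, because the annotation at hand is of another build.

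Groups were taken from the sample titles, since cell type tags of 3 E16 samples stood out of step with their titles. The comparisons, the rule for named genes, the gene lists and the alternatives were fixed before the data were examined, except where a setting is said to have been chosen after seeing the data. A gene was tested when it lay above the percentile 25 of all values (6.30) in at least as many arrays as the smallest group compared. Linear models for each gene were fitted with the blanks left out and moderated by limma 3.58.1 in R 4.3.3, with the reading packages jsonlite 2.0.0 and data.table (version 1.17.8), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. For genes without blanks the fit was checked to equal that of limma's own functions. GTML tumours were fitted with P7 cerebella, the orthotopic tumours were fitted together, the 18 tumours and cultures of the transplant series shared a model with origin as an additive term, and orthotopic tumours were compared with GTML tumours directly. Origins without replicates were assumed to vary like the replicated groups.

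There were 28 gene lists of pathways, medulloblastoma subgroups and cell types with 323 members, 277 of them measured. A list of erythroid genes had 2 measured members and was not tested. The other 27 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The score of a list in an array is the mean log2 level of its genes. Named genes were the 6 with the largest rise and the 6 with the largest fall among genes past the test whose groups did not overlap (passing over clone names, predicted genes and olfactory, vomeronasal and small RNA genes), 2 called genes of each list that passed, and 12 genes fixed in advance, of which some are not reported here. No genes were named by this rule for the test of origin beyond the fixed ones. Single values were compared by exact permutation, and relations between scores by 100000 permutations.

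Alternatives were no filter and a stricter filter (percentile 50, 8.00), the mean of all probes of a gene, quantile normalization, centring of arrays on their medians, a moderated test with trend and robust settings, array weights, all 56 arrays in a single model, replicate numbers as a block, and leaving out each replicate of groups of up to 5 arrays. Added after seeing the data were filled blanks, leaving out 4 GTML tumours (also for the relations between scores), leaving out both P0C GFP NSC arrays, leaving out the forebrain arrays and leaving out the 3 orthotopic tumours numbered 1 from the comparison with tumour cells. A fit of 5 GTML tumours of the same numbers as the cerebella, without a block, was also added then. The models were tested on simulated data in which 200 genes were changed: a change of 2 log2 units was recovered in 99% of genes for GTML tumours against P7 cerebella, 82% for P0C against E16C tumours, 93% for tumours against GFP NSCs, 73% for N-myc against GFP NSCs and 88% for tumour cells against tumours. A change of 1 log2 unit was recovered in 90%, 26%, 60%, 17% and 40%. The simulated genes varied independently of each other, without arrays that stand apart, so these shares need not hold for the real data.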

Results

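Expression was measured on Affymetrix whole-transcript arrays in 56 samples of FVB/N mouse tissue and cells, each on its own array. There were 32 medulloblastomas from GTML mice, in which a tetracycline-controlled MYCN transgene is driven in the brain from a glutamate transporter promoter, and 5 cerebella taken at postnatal day 7 (P7) from GTML mice given doxycycline, which keeps the transgene off. There were also 9 orthotopic tumours, grown from neural stem cells (NSCs) that carried a mutation-stabilised N-myc and had been transplanted into the brain. Their NSCs came from cerebellum at embryonic day 16 (E16C, n = 3), cerebellum at postnatal day 0 (P0C, n = 3) or forebrain at postnatal day 0 (P0F, n = 3). The remaining 10 arrays were of cultured cells without replicates: cells grown out of an E16C, a P0C, a P0F and a GTML tumour, N-myc NSCs of E16C and P0C origin, and GFP control NSCs of E16C, P0C (a GFP-sorted and an unsorted sample) and P0F origin. The comparisons ask how N-myc-driven tumours differ from normal cerebellum at P7, how the region and age of the NSC of origin show in the tumour, and what separates tumours from the cells they came from and the cells grown out of them. The sample titles do not say whether the 3 tumours of an origin grew from separate NSC cultures, nor at which site in the brain. Differences between origins may therefore include those of culture and site. The titles of the tumour cell cultures call their source tumours MB for E16C and P0C and glioma for P0F. The titles of the 9 orthotopic tumours themselves give no such name. Differences between forebrain and cerebellar origin may thus also be those between tumours named as different kinds. Levels are log2 values throughout, differences are log2 units unless a fold is named, and the number of arrays limits the precision of every value. A level under 6.30 lies below percentile 25 of all values, where background signal can hold a probe up, so a difference against such a level is that of the measured values and may understate that of the transcripts.

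Photoreceptor and Group 3 marker genes were higher in GTML tumours than in P7 cerebella (9 of 11, adjusted p = 0.000458, adjusted p = 0.171 with an estimated correlation), although 4 of the 32 tumours scored below the other 28. Crx (probe 6965592), the homeobox factor that switches on photoreceptor genes, stood at 12.15 ± 1.54 (SD, n = 32) in tumours and 6.25 ± 0.096 (SD, n = 5) in cerebella, a level under 6.30 (difference 5.90, SE 0.67, limma adjusted p = 5.27e-09). Other photoreceptor genes rose with it: Rbp3, the retinoid-binding protein between photoreceptors and pigment epithelium, by 5.31 (limma adjusted p = 3.7e-08), Sag (rod arrestin) by 5.14, the cone transducin subunit Gnb3 by 5.02, Mpp4 by 4.93 and Impg2 by 5.59. Otx2, the homeobox factor upstream of Crx and a marker of Group 3 and Group 4 medulloblastoma, was already high in cerebella at 10.25 ± 0.11 (SD, n = 5) and reached 12.58 ± 1.52 (SD, n = 32) in tumours (limma adjusted p = 0.00302). Genes of granule neuron precursors went the other way, measured against cerebella of a single age, P7. Zic1, a factor of granule neuron precursors, fell 33.8-fold (7.64 ± 1.32 against 12.72 ± 0.14; log2 -5.08, SE 0.58), Barhl1 fell by 3.27 and Atoh1, the factor that keeps granule precursors proliferating, fell by 2.69 (limma adjusted p = 3.21e-22). Among the other strong falls were Glra2 (a glycine receptor subunit, -4.86), Ptn (pleiotrophin, -4.47), Gap43 (a growth cone protein, -4.30), Grm3 (a glutamate receptor, -4.25) and Ednrb (the endothelin B receptor, -4.23). In Crx, Rbp3, Sag, Gnb3, Mpp4, Zic1, Barhl1, Atoh1, Glra2, Ptn, Gap43, Grm3 and Ednrb no tumour lay within the range of the cerebella. Of 12275 genes tested with limma, 7082 passed adjusted p 0.05, 4036 of them higher and 3046 lower in tumours, and 1845 of the 7082 also differed at least 2-fold, 583 higher and 1262 lower. With arrays centred on their medians the higher share was 69.5%, against 57% as deposited, and the median difference over all genes was 0.25 against 0.10.

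**Figure D1:**
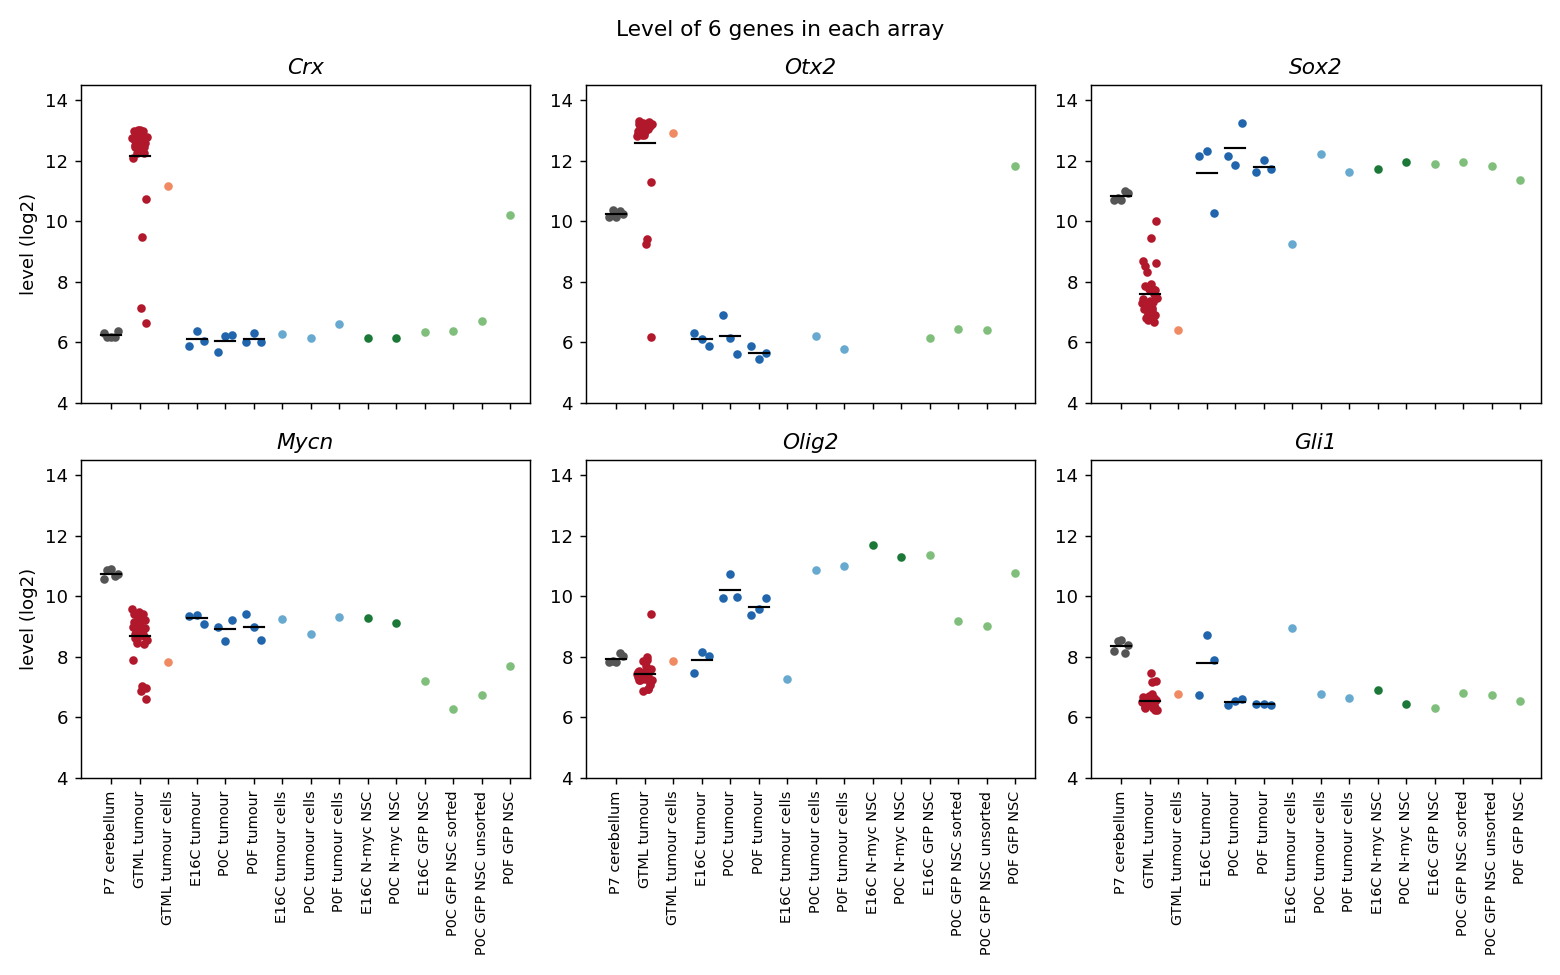
Level (log2, vertical axis) of Crx, Otx2, Sox2, Mycn, Olig2 and Gli1 in each array, by group along the horizontal axis; each point is an array and each black line the mean of a group of several arrays. Crx averaged 12.15 in GTML tumours and 6.25 in P7 cerebella, Sox2 averaged 11.93 in the 9 orthotopic tumours and 7.59 in GTML tumours, and the P0F GFP NSC array held Otx2 at 11.82.

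Of the 27 gene lists tested with camera, 4 were higher and 15 lower in GTML tumours than in P7 cerebella. Photoreceptor and Group 3 markers were higher (9 of 11 measured genes up, none down, median 2.54, adjusted p = 0.000458, adjusted p = 0.171 with an estimated correlation). Ribosome biogenesis and nucleotide synthesis genes induced by Myc were higher (18 of 18 up, median 0.95, adjusted p = 5.81e-06, adjusted p = 0.253 with an estimated correlation). So were immediate early and heat shock genes (6 of 8 up, adjusted p = 0.00466, adjusted p = 0.155 with an estimated correlation). Lymphocyte genes were higher (6 of 7 up, adjusted p = 0.0157, adjusted p = 0.253 with an estimated correlation). Gnl3 (nucleostemin) rose by 1.71 and Wdr12, of the ribosome assembly complex, by 1.41. Cd4 rose by 1.54, Cd8a by 1.43, Atf3 by 1.58 and Junb by 1.33. Of the lower lists, 5 held with an estimated correlation. The first was of sonic hedgehog (SHH) pathway and SHH medulloblastoma markers (7 of 9 down, median -1.80, adjusted p = 3.46e-06, 0.000383 with an estimated correlation). Granule neuron precursor genes were lower (10 of 12 down, median -2.30, adjusted p = 2.5e-08, 0.000263 with an estimated correlation). WNT targets were lower (7 of 9 down, adjusted p = 0.000426, 0.0409 with an estimated correlation). Cholesterol synthesis genes were lower (9 of 9 down, adjusted p = 1.29e-05, 0.0444 with an estimated correlation). Neural stem cell and radial glia genes were lower (9 of 12 down and 1 up, adjusted p = 0.000426, 0.0169 with an estimated correlation). Among their members were the WNT antagonists Sfrp1 (-3.99), Apcdd1 (-3.44) and Nkd1 (-2.86). The sterol enzymes Hmgcs1 (-1.89) and Fdft1 (-1.46) and the radial glial genes Fabp7 (-3.97) and Slc1a3 (-3.54) were others. The adjusted counts over the list alone were the same as those over all genes for these 9 lists.

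None of the other 10 lower lists, most of them of neuronal, glial and other cell types, held with an estimated correlation. Purkinje cell and GABAergic interneuron genes fell in 10 of 10 measured members (median -2.70, adjusted p = 1.3e-05, adjusted p = 0.145 with an estimated correlation), among them Calb1 (calbindin), which averaged 5.52 ± 1.84, a level under 6.30, against 11.93 ± 0.22, and Car8 (-5.70). Astrocyte genes fell in 8 of 9 (median -2.93, adjusted p = 0.000376, adjusted p = 0.253 with an estimated correlation), with Aldh1l1 at -4.08 and the water channel Aqp4 at -3.56. Oligodendrocyte genes fell in 7 of 8 (adjusted p = 0.00155, adjusted p = 0.253 with an estimated correlation; Cnp -2.72, Mag -2.59) and oligodendrocyte precursor genes in 7 of 7 (adjusted p = 0.000416, adjusted p = 0.108 with an estimated correlation; Gpr17 -3.25, Pdgfra -2.61). General neuronal genes fell in 6 of 9 (adjusted p = 0.0042, adjusted p = 0.253 with an estimated correlation; Stmn2 -3.55, Nefl -2.90). Choroid plexus genes fell in 3 of 4 (adjusted p = 0.00303, adjusted p = 0.116 with an estimated correlation), led by transthyretin, Ttr, at 7.17 ± 1.71 against 13.85 ± 0.25, and by Clic6 (-2.33). Hindbrain and cerebellar factors fell in 6 of 11 and rose in 1 (adjusted p = 0.00327, adjusted p = 0.108 with an estimated correlation; Meis1 -3.21), and Group 4 medulloblastoma markers fell in 4 of 5 (adjusted p = 0.00298, adjusted p = 0.0521 with an estimated correlation; Khdrbs2 -2.42, Eomes -1.90). Endothelial and pericyte genes fell in 5 of 12 (adjusted p = 0.00673, adjusted p = 0.253 with an estimated correlation; Cldn5 -2.71, Tek -1.68), and Notch pathway genes fell in 5 of 9 and rose in 1 (adjusted p = 0.0329, adjusted p = 0.116 with an estimated correlation; Notch1 -1.45, Hes5 -1.29). The 8 lists that did not pass were cell cycle (adjusted p = 0.454, median 0.33), mature granule neurons (0.267), microglia and macrophages (0.212), interferon response and MHC class I (0.098), forebrain factors (0.113), fibroblasts and meninges (0.0531), p53 targets (0.326) and hypoxia and glycolysis (0.303). The lymphocyte call was lost when arrays were quantile normalized again (adjusted p = 0.0672).

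The signal of the mouse Mycn probe was lower, not higher, in GTML tumours: 8.68 ± 0.78 (SD, n = 32) against 10.75 ± 0.14 (SD, n = 5), a fall of 4.18-fold (limma adjusted p = 5.64e-06). The transgene is human MYCN, and how far the mouse probe reads it is not known here. The cerebella were of a single age, P7, with a mean granule precursor score of 10.58 and a cell cycle score of 9.98. GTML tumours averaged 8.14 and 10.32. The differences in this paragraph are relative to that tissue and can reflect its state as well as that of the tumours. The SHH target Gli1 fell by 1.80 (6.56 ± 0.28 against 8.36 ± 0.19) and the SHH receptor Ptch1 by 0.77 (limma adjusted p = 0.000203). The stem cell factors Sox2 (7.59 ± 0.79 against 10.82 ± 0.13) and Sox9 (-1.01) fell, as did the astrocyte filament Gfap (-1.67, limma adjusted p = 0.0102). Olig2 differed by -0.48 (limma adjusted p = 0.0337), a call lost with quantile normalization (0.143) or centred arrays (0.132), and the proliferation marker Mki67 by 0.18 (limma adjusted p = 0.764). The 4 GTML arrays of replicates 20, 22, 30 and 31 held low photoreceptor scores, 6.55, 7.58, 7.40 and 6.40 against 8.19 to 9.32 in the other 28, and replicates 20, 22 and 30 held low cell cycle scores, 6.99, 7.30 and 8.96 against 9.73 to 10.91. Replicates 20 and 30 held the genes of mature neurons, astrocytes and oligodendrocytes above all of the other 28 tumours; the Purkinje score was 11.28 and 11.07, against at most 7.71. Without these 4 arrays, a setting chosen after seeing the data, 9054 genes passed, 7029 of them among the 7082. The cell cycle list then passed at the preset correlation of 0.01 (mean 0.61, adjusted p = 0.00247) with Mki67 up by 0.45 (limma adjusted p = 0.00437). The lymphocyte (adjusted p = 0.064) and Notch (adjusted p = 0.0726) lists did not pass. Over all 32 tumours the estimated correlation of the cell cycle list was 0.954, far above the preset value.

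**Figure D2:**
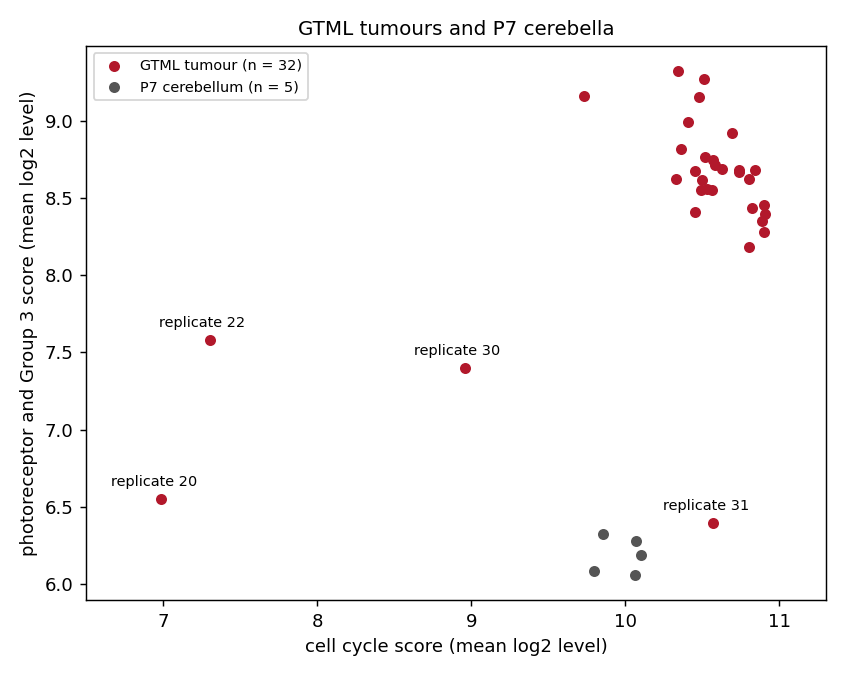
Photoreceptor and Group 3 score (vertical axis) against cell cycle score (horizontal axis), both as mean log2 level over the genes of the list, for 32 GTML tumours and 5 P7 cerebella; each point is an array. The 28 tumours without a replicate number lie between 8.19 and 9.32 on the vertical axis, and the numbered replicates 20, 22, 30 and 31 lie at 6.55, 7.58, 7.40 and 6.40.

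Relations of the SHH score, a mean over the measured SHH genes, with 7 other list scores were planned over all 32 GTML tumours. There the SHH score fell as the photoreceptor score rose (Pearson r = -0.821, adjusted permutation p = 7e-05; Spearman rho = -0.531, adjusted permutation p = 0.00724) and rose with the WNT target score (r = 0.788, adjusted permutation p = 7e-05; rho = 0.534, adjusted permutation p = 0.00724). Without the 2 tumours farthest from the median SHH score r was -0.745 and 0.493. Cell cycle (r = -0.767, adjusted permutation p = 0.000653), Myc-induced (r = -0.734, adjusted permutation p = 0.000805) and astrocyte scores (r = 0.431, adjusted permutation p = 0.0244) passed by r but not by rho (0.13, 0.137 and 0.0748, adjusted permutation p = 0.667, 0.667 and 0.797). Without those 2 tumours r was -0.291, -0.309 and 0.203, so these 3 relations rested on them. Microglia had r = -0.336 (adjusted permutation p = 0.0652) and rho = -0.422 (adjusted permutation p = 0.0399), and granule precursors r = -0.0565 (adjusted permutation p = 0.726) and rho = 0.0154. Within the 28 tumours without replicates 20, 22, 30 and 31, a restriction chosen after seeing the data, the photoreceptor (r = -0.322, rho = -0.286, adjusted permutation p = 0.13) and WNT relations (r = 0.36, rho = 0.423, adjusted permutation p = 0.105) did not pass. The sign of r turned for the cell cycle (r = 0.531, permutation p = 0.00278, adjusted p = 0.0195; rho = 0.551, permutation p = 0.00264) and Myc-induced scores (r = 0.491, permutation p = 0.00697, adjusted p = 0.0244; rho = 0.495, permutation p = 0.00763), with 0.447 and 0.406 without the 2 farthest tumours. Microglia (r = -0.405, rho = -0.415, adjusted permutation p = 0.0723), astrocytes (r = -0.129, rho = -0.0903, adjusted permutation p = 0.599) and granule precursors (r = 0.103, rho = 0.0219, adjusted permutation p = 0.607) did not pass there, so that each relation that passed by r depended on the 4 arrays.

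P0C tumours differed from E16C tumours, the same region at a younger age of origin, in genes of the oligodendrocyte lineage. Omg, the oligodendrocyte myelin glycoprotein, stood at 10.71 ± 1.08 (SD, n = 3) in P0C and 5.28 ± 0.78 (SD, n = 3) in E16C tumours, a level under 6.30 (difference 5.43, SE 0.67, limma adjusted p = 0.0128). Ugt8a, which makes the myelin lipid galactosylceramide, rose by 4.26 (limma adjusted p = 0.0257), the myelin enzyme Cnp by 4.21 (limma adjusted p = 0.0478) and Olig2, the factor that specifies the lineage, by 2.32 (10.21 ± 0.46 against 7.89 ± 0.38, limma adjusted p = 0.0128). The matrix protein Tnr (4.51), the adhesion molecule Ncam2 (4.53) and Tmeff2 (4.24) rose as well. E16C tumours held more of Mki67 (9.49 ± 0.24 against 10.72 ± 0.20, log2 -1.23, limma adjusted p = 0.031), of the DNA polymerase subunit Pola1 (-1.36), of the BMP receptor Bmpr1b (-2.20), and of Ttc23 (-2.76), Fbln2 (-2.37), Atp10a (-2.15) and Sardh (-1.41). In each of these 14 genes the 3 arrays of either group did not overlap. Oligodendrocyte genes were higher in P0C tumours (3 of 8 past the test, 8 of 8 adjusted over the list alone, median 2.85, adjusted p = 2.15e-08, adjusted p = 0.0527 with an estimated correlation). The oligodendrocyte score ran from 9.10 to 11.48 in P0C tumours, against 6.73 in P0C tumour cells and 7.22 in P0C N-myc NSCs. Whether the tumour cells or neighbouring brain tissue held these genes was not tested. Oligodendrocyte precursor genes were higher too (1 of 7, 4 over the list alone, median 2.52, adjusted p = 2.72e-06, adjusted p = 0.0527 with an estimated correlation). Endothelial genes were higher with 0 of 12 past the limma test (median 0.50, adjusted p = 0.0234, adjusted p = 0.628 with an estimated correlation). Cell cycle genes were lower as a group (1 of 20 past the test, median -0.66, adjusted p = 2.55e-06, adjusted p = 0.106 with an estimated correlation). Granule neuron precursor genes were lower (0 of 12 by limma, 1 over the list alone, median -0.94, adjusted p = 0.00021, adjusted p = 0.0921 with an estimated correlation). So were Myc-induced genes (0 of 18 by limma, median -0.52, adjusted p = 0.000258, adjusted p = 0.536 with an estimated correlation). Hindbrain factors were lower (0 of 11 by limma, 1 over the list alone, adjusted p = 0.0234, adjusted p = 0.547 with an estimated correlation). The last lower list was cholesterol synthesis (0 of 9 by limma, adjusted p = 0.0234, adjusted p = 0.0527 with an estimated correlation). Gli1 stood at 6.53 ± 0.090 against 7.79 ± 0.99 (limma adjusted p = 0.223), Atoh1 at 6.26 (n = 2) against 8.43 ± 2.04 (limma adjusted p = 0.351), and the SHH list did not pass (median -0.68, adjusted p = 0.0574). Mycn differed by -0.37 (limma adjusted p = 0.574) and Sox2 by 0.84 (limma adjusted p = 0.52).

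Of 11917 genes tested between P0C and E16C tumours with limma, 84 passed, 66 higher in P0C (78.6% as deposited, 66% with arrays centred on their medians) and 18 lower, and 1714 had an unadjusted p under 0.05. The count was 37 without P0C replicate 3, 35, 38 and 230 without E16C replicates 1, 2 and 3, 36 with replicate numbers as a block and 8 with only these 6 arrays in the fit. It was 989 with all 56 arrays in a single model. Omg, Ncam2, Bmpr1b, Atp10a and Olig2 passed whichever array was left out, and so did the oligodendrocyte, oligodendrocyte precursor, cell cycle and granule precursor lists. Mki67 did not, with an adjusted limma p of 0.0749 and 0.0653 without P0C replicates 1 and 3 and of 0.0873 and 0.0829 without E16C replicates 1 and 2. For Ugt8a the same 4 values were 0.0663, 0.0634, 0.0759 and 0.0821. The Myc-induced list was lost without P0C replicate 2 (adjusted p = 0.0756), the hindbrain list without P0C replicate 1 (0.125) or E16C replicate 1 (0.242). The endothelial list was lost without P0C replicate 2 (0.369), E16C replicate 1 (0.15) or E16C replicate 3 (0.0746), and the cholesterol list was lost without the same 3 arrays (0.0597, 0.0649 and 0.0914) and under quantile normalization (0.0566).

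P0F tumours differed from P0C tumours in interferon-stimulated genes and, again, in oligodendrocyte genes. Ifit1, an interferon-induced RNA-binding protein, stood at 11.26 ± 1.06 (SD, n = 3) in P0F and 6.26 ± 0.96 (SD, n = 2, the third array blank) in P0C tumours, a level under 6.30 (difference 5.00, SE 0.71, limma adjusted p = 0.0253). The chemokines Cxcl10 (4.55, limma adjusted p = 0.0105) and Cxcl13 (4.19), the cytosolic RNA sensor Ifih1 (4.44, limma adjusted p = 0.0239), and Oasl1 (4.06), Oasl2 (3.87) and Samd9l (4.06), all interferon-induced, rose with it. Myelin basic protein, Mbp, stood at 7.84 ± 0.31 against 11.46 ± 0.99 (log2 -3.63, limma adjusted p = 0.021), and Ugt8a (-3.89) and Gal3st1 (-3.41), which make the galactolipids of myelin, fell too. Ednrb was 18-fold lower (8.14 ± 0.30 against 12.31 ± 0.49, limma adjusted p = 0.00615), Tmeff2 fell by 3.94 and Tnr by 3.40. Interferon response and MHC class I genes rose as a list (5 of 9 past the test, 9 of 9 adjusted over the list alone, median 2.69, adjusted p = 6.55e-11, adjusted p = 0.133 with an estimated correlation). Microglia and macrophage genes were higher by a smaller amount (0 of 12, median 0.50, adjusted p = 0.0331, adjusted p = 0.843 with an estimated correlation). Oligodendrocyte genes were lower (2 of 8, 5 over the list alone, median -2.62, adjusted p = 7.93e-07, adjusted p = 0.203 with an estimated correlation). Oligodendrocyte precursor genes were lower (0 of 7 by limma, 2 over the list alone, median -1.10, adjusted p = 0.0074, adjusted p = 0.43 with an estimated correlation). So were endothelial genes (0 of 12 by limma, median -0.64, adjusted p = 0.0074, adjusted p = 0.839 with an estimated correlation). Olig2 differed by -0.58 (limma adjusted p = 0.371), Gfap by 1.22 (limma adjusted p = 0.289), Sox9 by 1.26 (limma adjusted p = 0.277) and Mycn by 0.093 (limma adjusted p = 0.907).

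In the limma comparison of P0F with P0C tumours 141 of 11917 genes passed, 88 higher and 53 lower in P0F, and 1941 had an unadjusted p under 0.05. The count fell to 0 without P0F replicate 1 (1350 unadjusted). It was 36 and 59 without P0F replicates 2 and 3, 12, 251 and 56 without P0C replicates 1, 2 and 3. It was 25 with replicate numbers as a block, 238 with only these 6 arrays in the fit, 674 with array weights and 1329 with all 56 arrays in a single model. None of the 13 named genes passed whichever array was left out, while the interferon and oligodendrocyte lists did. The microglia list was lost without P0F replicate 1 (adjusted p = 0.155) or P0C replicate 3 (0.587), and the oligodendrocyte precursor and endothelial lists without P0C replicate 2 (0.239 for both).

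The interferon genes also separated P0F from E16C tumours. Ifit1 stood at 11.26 ± 1.06 (SD, n = 3) against 6.36 ± 0.84 (SD, n = 3; limma adjusted p = 0.0334), and Trim30a (4.12), Oasl1 (4.04), Oasl2 (3.98), Cxcl10 (3.95) and Cxcl13 (3.89) rose as well. Among the lower genes in P0F tumours were Mki67 (9.49 ± 0.061 against 10.72 ± 0.20, limma adjusted p = 0.0473), the kinetochore protein Nuf2 (2.82-fold), the mitotic kinase Pbk (-1.46) and the linker histone H1f5 (-1.46), along with Fam122b (-1.67), Praf2 (-1.48) and Csrp2 (-1.41). Interferon genes rose as a list (3 of 9 past the test, 9 over the list alone, median 2.74, adjusted p = 7.81e-13, 0.0206 with an estimated correlation). SHH genes were lower (0 of 9, median -0.98, adjusted p = 0.00547, 0.0206 with an estimated correlation). Cholesterol synthesis genes were lower (0 of 9, median -0.47, adjusted p = 0.000693, 0.00147 with an estimated correlation). Of these 3 lists, the interferon and cholesterol lists also passed fry, a second list test that was planned (fry adjusted p = 0.0388 for both). The SHH list did not (fry adjusted p = 0.176). Microglia genes were higher (0 of 12, median 0.72, adjusted p = 3.39e-05, adjusted p = 0.289 with an estimated correlation). Cell cycle genes were lower (1 of 20, median -0.41, adjusted p = 0.000366, adjusted p = 0.289 with an estimated correlation). Granule precursor genes were lower (0 of 12 by limma, 2 over the list alone, adjusted p = 0.00171, adjusted p = 0.178 with an estimated correlation). Hypoxia genes were lower (0 of 9 by limma, 1 over the list alone, adjusted p = 0.0237, adjusted p = 0.355 with an estimated correlation). Olig2 stood at 9.63 ± 0.28 against 7.89 ± 0.38 (limma adjusted p = 0.0575), Gli1 differed by -1.36 (limma adjusted p = 0.233) and Atoh1 by -2.32 (limma adjusted p = 0.332). By limma 33 of 11916 genes passed, 26 higher and 7 lower, and 1412 had an unadjusted p under 0.05. The count fell to 0 without P0F replicate 1 (1121 unadjusted), without E16C replicate 1 (1374 unadjusted) and with replicate numbers as a block (1375 unadjusted). It was 18 and 20 without P0F replicates 2 and 3, 5 and 9 without E16C replicates 2 and 3, 64 with array weights and 599 with all 56 arrays in a single model. None of the 13 named genes passed whichever array was left out, the Mki67 call was lost with quantile normalization (0.0633) or centred arrays (0.0508), and of the 7 lists the hypoxia list was lost without P0F replicate 2 (adjusted p = 0.0643) or E16C replicate 1 (0.152).

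**Figure D3:**
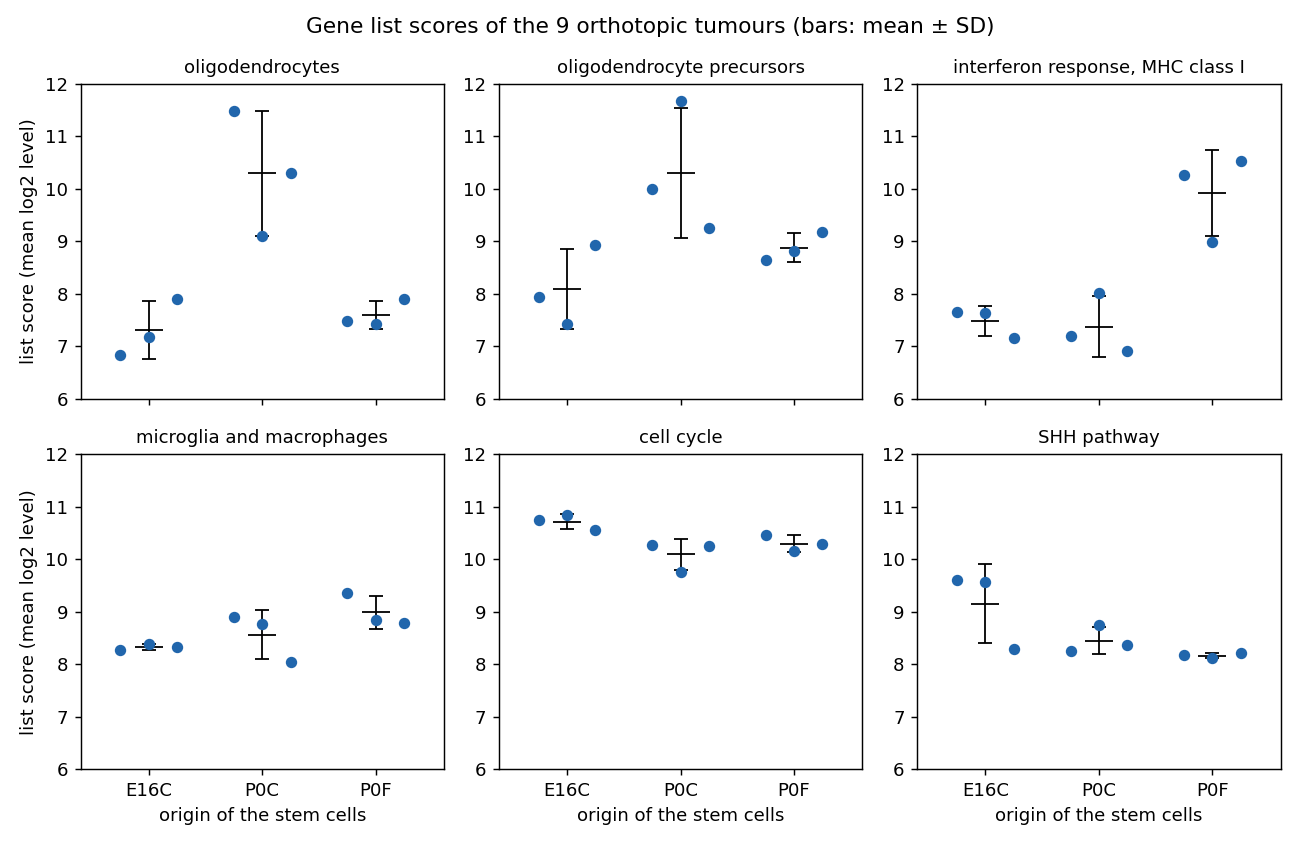
List score (mean log2 level over the genes of a list, vertical axis) of the 9 orthotopic tumours by origin of the stem cells (horizontal axis) for 6 lists; each point is a tumour, and bars give the mean and SD of 3. The oligodendrocyte score averaged 10.29 in P0C tumours against 7.30 in E16C and 7.60 in P0F tumours, and the interferon score averaged 9.92 in P0F tumours against 7.48 in E16C and 7.37 in P0C tumours.

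The SHH score, over 8 genes measured in all 9 tumours, averaged 9.16 ± 0.76 (SD, n = 3) in E16C, 8.45 ± 0.26 in P0C and 8.17 ± 0.047 in P0F tumours. E16C replicates 1 and 2 stood at 9.61 and 9.58 and replicate 3 at 8.29, within the range of the P0C tumours (8.25 to 8.74). The differences were -0.70 for P0C minus E16C (exact two-sided permutation p = 0.3), -0.29 for P0F minus P0C (exact permutation p = 0.1) and -0.99 for P0F minus E16C (exact permutation p = 0.1), where 3 arrays against 3 allow no p below 0.1. Likeness to GTML tumours was taken as the correlation across 12445 genes of each tumour's departure from the mean of the 9 orthotopic tumours with the departure of GTML tumours from P7 cerebella, and it ran from -0.265 in P0C replicate 2 to 0.155 in E16C replicate 3. Genes are not independent replicates, so the tumours were compared by permutation. The mean correlation differed by 0.0221 between the 6 cerebellar and the 3 forebrain tumours (exact permutation p = 0.833, adjusted p = 0.833). It differed by -0.216 for P0C minus E16C (exact permutation p = 0.1, adjusted p = 0.4) and by 0.086 for P0F minus P0C (exact permutation p = 0.5, adjusted p = 0.667). For P0F minus E16C it differed by -0.13 (exact permutation p = 0.3, adjusted p = 0.6). These 4 tests were two-sided.

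Compared with GFP NSCs of their origins, orthotopic tumours held higher levels of genes of microglia and vessels. The complement gene C1qb, made by microglia, stood at 10.56 ± 0.48 (SD, n = 9) in tumours and 6.65 ± 0.68 (SD, n = 4) in GFP NSCs, 15.1-fold higher (limma adjusted p = 6.63e-06). C1qc (3.13), the lysosomal protease Ctss (3.78), the complement receptor C3ar1 (3.69) and Ly86 (3.55) rose with it. Vessel genes rose too, with Emcn (endomucin) up by 3.25, Cdh5 (VE-cadherin) by 2.39 and the pericyte gene Rgs5 by 2.62, as did the lipocalin Apod (4.44, limma adjusted p = 1.18e-05) and the astrocyte filament Gfap (3.07, limma adjusted p = 0.00166). Mycn was 4.02-fold higher in tumours (9.06 ± 0.34 against 6.98 ± 0.61, limma adjusted p = 4.75e-05). Enzymes of cholesterol synthesis fell, among them Fdft1 (9.70 ± 0.39 against 11.90 ± 0.38, limma adjusted p = 1.21e-05) and Idi1 (-2.05), and so did the fatty acid desaturase Scd1 (-3.15), Clic5 (-3.75), Ephx1 (-3.24), the pentraxin Nptx1 (-3.19), the galectin Lgals1 (-2.72) and Cdh13 (-2.63). Microglia and macrophage genes were higher in 11 of 12 members (median 1.68, adjusted p = 6.6e-17, 0.0105 with an estimated correlation). Endothelial and pericyte genes were higher in 9 of 12 (11 adjusted over the list alone, median 1.59, adjusted p = 1.88e-10, 0.0166 with an estimated correlation). Cholesterol synthesis genes were lower in 9 of 9 (median -1.53, adjusted p = 8.52e-13, 0.00185 with an estimated correlation). Oligodendrocyte genes were higher (3 of 8, adjusted p = 0.000791, adjusted p = 0.383 with an estimated correlation; Mbp 2.81, Cldn11 2.24). The oligodendrocyte score was 10.29 in P0C tumours, against 7.30 in E16C and 7.60 in P0F tumours and 6.94 to 7.30 in GFP NSCs. Fibroblast genes were higher (2 of 8, 3 over the list alone, adjusted p = 0.00208, adjusted p = 0.273 with an estimated correlation; Dcn 3.22, Col1a2 0.71). Myc-induced genes were higher (3 of 18, adjusted p = 0.000681, adjusted p = 0.438 with an estimated correlation; Wdr12 1.01, Ddx21 0.92). Immediate early and heat shock genes were lower (2 of 8, 5 over the list alone, adjusted p = 0.00218, adjusted p = 0.383 with an estimated correlation; Atf3 -1.75, Dnajb1 -1.58). Otx2 differed by -1.79 (limma adjusted p = 0.156) and Sox2 by 0.28 (limma adjusted p = 0.716).

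The limma comparison of tumours with GFP NSCs called 1408 of 12175 genes, 519 higher and 889 lower in tumours, so that 36.9% were higher, against 60.3% with quantile normalization and 55.1% with arrays centred on their medians. The count was 4557 with array weights and 2571 with all 56 arrays in a single model. Both P0C GFP NSC arrays held high immediate early and heat shock scores, 11.50 sorted and 11.53 unsorted against 9.03 in E16C and 8.93 in P0F GFP NSCs, with lower cell cycle scores (9.78 and 9.86 against 10.70 and 11.01) and lower Myc-induced scores (9.35 and 9.31 against 10.54 and 10.41). The count was 563 without the sorted and 696 without the unsorted array, and Wdr12 (0.151 and 0.16), Mbp (0.0961 and 0.08), Cldn11 (0.0637 and 0.0544) and Atf3 (0.157 and 0.162) did not pass there. Without E16C GFP NSCs the calls of Wdr12 (0.0576), Dcn (0.0502) and Col1a2 (0.0507) were lost. Atf3 was also lost with quantile normalization (0.0583) or centred arrays (0.0591). Without both, a setting chosen after seeing the data, 333 genes passed, 232 of them among the 1408, the Myc-induced (adjusted p = 0.602), oligodendrocyte (0.107) and immediate early (0.864) lists were lost, and the microglia, endothelial, fibroblast and cholesterol lists kept their calls. Emcn (0.0652), Nptx1 (0.0597), Cdh13 (0.0751), Ddx21 (0.113), Rgs5 (0.0503) and Dnajb1 (0.114) did not pass either in that setting. The P0F GFP NSC array also held Otx2 at 11.82 and Crx at 10.19, genes of the GTML tumours that the other GFP NSCs did not hold at these levels.

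N-myc NSCs, which carried the oncogene but had not been transplanted, differed from GFP NSCs in Mycn itself. Mycn stood at 9.21 ± 0.12 (SD, n = 2) against 6.98 ± 0.61 (SD, n = 4), 4.66-fold higher (log2 2.22, SE 0.30, limma adjusted p = 0.0246), and was the single gene of 12557 to pass, with 1068 at an unadjusted p under 0.05. With all 56 arrays in a single model 432 genes passed, and with array weights 1388. Whether the sorted and unsorted P0C GFP NSC arrays came from separate cultures is not given in the sources used here, so the 4 arrays are not shown to be independent cultures. Myc-induced genes of ribosome biogenesis and nucleotide synthesis were higher as a list (0 of 18 past the limma test, 2 adjusted over the list alone, median 0.67, adjusted p = 8.23e-08, adjusted p = 0.515 with an estimated correlation). Cell cycle genes were higher (0 of 20 by limma, median 0.47, adjusted p = 0.00135, adjusted p = 0.72 with an estimated correlation). Immediate early and heat shock genes were lower (0 of 8 by limma, 2 over the list alone, median -1.56, adjusted p = 6.73e-05, adjusted p = 0.515 with an estimated correlation). Cholesterol synthesis genes were lower (0 of 9 by limma, median -0.47, adjusted p = 0.00562, adjusted p = 0.515 with an estimated correlation). The p53 targets were lower (0 of 11 by limma, median -0.40, adjusted p = 0.0312, adjusted p = 0.72 with an estimated correlation). The P0C GFP NSC pair had immediate early and heat shock scores of 11.50 and 11.53. Without both arrays, a setting chosen after seeing the data that leaves P0C N-myc NSCs without a control of their origin, the mean difference went from 0.66 to 0.22 for the Myc-induced list (adjusted p = 0.0942) and from 0.47 to 0.089 for the cell cycle list (0.944). It went from -0.43 to -0.14 for cholesterol synthesis (0.321), from -1.64 to -0.079 for the immediate early list (0.633) and from -0.72 to -1.07 for the p53 list (0.00062). The p53 target score was 9.95 in P0F GFP NSCs, against 8.33 to 8.86 in the other 5 arrays, and without that array the p53 list was lost (0.591), as it was with quantile normalization (0.0514). Mycn differed by 1.89 without both P0C GFP arrays (limma adjusted p = 0.414). Its adjusted limma p was 0.0714 without E16C GFP NSCs, 0.0814 and 0.108 without the sorted and unsorted P0C GFP NSCs, and 1 without P0C N-myc NSCs. The count was 0 by limma in these 4 fits (1748, 521, 567 and 285 unadjusted), 10 without E16C N-myc NSCs and 2 without P0F GFP NSCs. The Myc-induced (0.29) and cell cycle (0.56) lists were lost without P0C N-myc NSCs, and the cholesterol (0.129) and p53 (0.656) lists without E16C N-myc NSCs.

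Cells grown out of the orthotopic tumours held less of the genes of microglia and vessels. C1qb stood at 6.44 ± 0.29 (SD, n = 3) in tumour cells and 10.56 ± 0.48 (SD, n = 9) in tumours (log2 -4.12, limma adjusted p = 1.9e-05), C1qc fell by 3.26 and Ctss fell by 3.99. The vascular receptor Kdr fell by 2.45 and Rgs5 by 2.52. Gfap stood at 6.07 ± 0.27 against 10.31 ± 0.86 (limma adjusted p = 0.000514), and the lipid carriers Apod (-4.47) and Apoe (-3.89) and Ndrg2 (-3.85) fell. Enzymes of sterol and fatty acid synthesis rose in culture: Msmo1 (11.39 ± 0.13 against 9.11 ± 0.25, limma adjusted p = 2.35e-05), Idi1 (2.26), Dhcr7 (1.43) and Scd1 (2.44), along with Lgals1 (2.44), the kinase Frk (5.27-fold) and Sting1 (2.20). The mitotic kinases Plk1 (1.23, limma adjusted p = 0.00138) and Bub1 (1.38) rose. Microglia genes fell in 11 of 12 members (12 adjusted over the list alone, median -2.13, adjusted p = 6.28e-23, 0.00125 with an estimated correlation). Endothelial genes fell in 6 of 12 (11 over the list alone, median -1.41, adjusted p = 1.31e-12, 0.00485 with an estimated correlation). Astrocyte genes fell in 2 of 9 (Gfap, and Aqp4 at -2.06; adjusted p = 0.000865, 0.00979 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 9 (9 over the list alone, median 1.21, adjusted p = 1.58e-12, 0.00125 with an estimated correlation). Cell cycle genes were higher (2 of 20, 4 over the list alone, adjusted p = 1.03e-05, adjusted p = 0.252 with an estimated correlation). Oligodendrocyte genes were lower (0 of 8 by limma, 3 over the list alone, adjusted p = 0.000225, adjusted p = 0.252 with an estimated correlation). Notch pathway genes were lower (1 of 9, Hey2 at -2.46, 2 over the list alone, adjusted p = 0.00299, adjusted p = 0.212 with an estimated correlation). Fibroblast genes were lower (1 of 8, Col1a2 at -0.68, adjusted p = 0.00553, adjusted p = 0.252 with an estimated correlation). Mycn differed by 0.057 (limma adjusted p = 0.927) and Mki67 by 0.48 (limma adjusted p = 0.313).

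Myc-induced genes (0 of 18, adjusted p = 0.0485, adjusted p = 0.745 with an estimated correlation) passed as higher in tumour cells. General neuronal genes passed as lower (0 of 9 by limma, adjusted p = 0.0262, adjusted p = 0.363 with an estimated correlation), as did Purkinje genes (0 of 7, adjusted p = 0.0499, adjusted p = 0.225 with an estimated correlation). These 3 calls were lost under quantile normalization (0.268, 0.0941 and 0.178). By limma 450 of 12372 genes passed, 211 higher in tumour cells and 239 lower, and with quantile normalization 33% were higher. The count was 129 without the P0C and 137 without the P0F tumour cells, 297 with quantile normalization, 1685 with array weights and 1706 with all 56 arrays in a single model. Without the P0C cells the fibroblast (0.0636), Myc-induced (0.11) and Purkinje (0.0934) lists were lost, and without the P0F cells the general neuronal (0.218), Myc-induced (0.0975) and Purkinje (0.104) lists. Lgals1, Msmo1, Idi1, Apod, Gfap, C1qb, Ctss, Apoe, Ndrg2, Plk1, C1qc, Kdr and Dhcr7 passed whichever tumour cell array was left out, and Scd1, Frk, Sting1, Bub1, Aqp4, Rgs5, Col1a2 and Hey2 did not. Without the P0C cells their adjusted limma p was 0.0669 for Scd1, 0.0721 for Frk, 0.227 for Sting1, 0.218 for Bub1, 0.0999 for Rgs5, 0.239 for Col1a2 and 0.226 for Hey2, and without the P0F cells it was 0.0854 for Aqp4. With quantile normalization Sting1 (0.0564), Bub1 (0.0531), Col1a2 (0.122) and Hey2 (0.0625) did not pass. The titles of the tumour cells number their source tumours as 1, so these cells may share an animal with a tumour among the 9, while the model treats all arrays as independent. Leaving out the 3 tumours numbered 1, a setting chosen after seeing the data, gave 392 genes, 298 of them among the 450, and the calls of Sting1 (0.0613) and Col1a2 (0.105) were lost.

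Whether the tumour against GFP NSC difference depended on origin was tested by a limma F test over the 3 origins, which 377 of 12409 genes passed, with 2687 at an unadjusted p under 0.05. Olig2 was among them (adjusted p = 0.00589): its tumour minus NSC difference was larger by 4.59 in P0C and by 2.35 in P0F than in E16C. The P0C value exceeds the Olig2 difference between P0C and E16C tumours given above, so part of it came from the GFP NSC arrays. There the oligodendrocyte precursor score was 9.44 in E16C, against 8.44 in sorted and 8.42 in unsorted P0C cells. Otx2 was another (adjusted p = 0.00305), with -0.16 in P0C and -6.11 in P0F, where the P0F GFP NSC array held Otx2 at 11.82 and P0F tumours averaged 5.66. Without the sorted or the unsorted P0C GFP NSC array 37 or 19 genes passed, and with array weights or all 56 arrays in a single model 2295 or 1711. Without the forebrain arrays, a setting chosen after seeing the data, 1 gene passed, the limbic system adhesion protein gene Lsamp, named here after its values were seen (P0C minus E16C difference of 4.30, SE 0.32, limma adjusted p = 0.0134). The E16C and P0F GFP NSCs were a single array each and the P0C pair a sorted and an unsorted sample, so these p-values rest on the spread of the other groups.

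Orthotopic and GTML tumours, both driven by N-myc, differed in many genes, although the labels give different labelling protocols for these arrays, so that the counts of genes and lists mix protocol with tumour type. Under the GTML protocol P7 cerebella held Sox2 at 10.82, Fabp7 at 12.42 and Crx at 6.25, and under that of the transplant series the P0F GFP NSC array held Otx2 at 11.82 and Crx at 10.19. For these genes neither protocol kept the level low, and Crx was also low under both. Otx2 stood at 5.99 ± 0.44 (SD, n = 9) in orthotopic and 12.58 ± 1.52 (SD, n = 32) in GTML tumours (limma adjusted p = 3.06e-14), and Crx at 6.08 ± 0.22 against 12.15 ± 1.54, both under 6.30 in orthotopic tumours, with the retinal membrane protein Rom1 lower by 2.74. Sox2 was 20.3-fold higher in orthotopic tumours (11.93 ± 0.78 against 7.59 ± 0.79, limma adjusted p = 3.78e-16). The radial glial lipid-binding protein Fabp7 was higher by 4.19, the SHH effector Gli3 by 3.53, the matrix proteoglycan Vcan by 3.70, Antxr1 by 3.85 and the protamine Prm1 by 4.24. Gckr (-3.39), the ryanodine receptor Ryr2 (-3.13), the neurofilament Nefh (-3.02) and Ebpl (-2.70) were lower. Notch1 (3.14), Hey2 (2.81), Pdgfra (2.64), Gpr17 (2.26), Olig2 (1.80), Ptch1 (2.82-fold, limma adjusted p = 8.12e-10), Sox9 (1.35) and Gfap (1.53) were higher, and Mycn differed by 0.38 (limma adjusted p = 0.226) and Mki67 by 0.77 (limma adjusted p = 0.0627). How far the mouse Mycn probe reads the human transgene is not known here, so the Mycn difference does not compare total N-myc. None of the 9 lists that passed held with an estimated correlation. Genes of oligodendrocyte precursors were higher (7 of 7 up, median 1.81, adjusted p = 0.000168, adjusted p = 0.0881 with an estimated correlation). So were those of neural stem cells (9 of 12 up, 2 down, adjusted p = 0.000568, adjusted p = 0.0625 with an estimated correlation). Notch pathway genes were higher (7 of 9 up, 1 down, adjusted p = 0.000957, adjusted p = 0.0881 with an estimated correlation). Interferon response genes were higher (7 of 9 up, adjusted p = 0.00367, adjusted p = 0.522 with an estimated correlation; Ifit1 2.06, Oasl2 1.53). Hindbrain factors were higher (10 of 11 up, 1 down, adjusted p = 0.00727, adjusted p = 0.253 with an estimated correlation; Zic1 2.10, Hoxa2 1.86). SHH markers were higher (8 of 9 up, adjusted p = 0.0212, adjusted p = 0.174 with an estimated correlation; Eya1 1.81, Boc 1.55). Forebrain factors were higher (6 of 9 up, 1 down, adjusted p = 0.0291, adjusted p = 0.522 with an estimated correlation; Dlx1 1.62, Dlx5 1.02). Photoreceptor and Group 3 markers were lower (9 of 12 down, median -2.30, adjusted p = 0.00128, adjusted p = 0.387 with an estimated correlation). Mature granule neuron genes were lower too (6 of 8 down, adjusted p = 0.0495, adjusted p = 0.749 with an estimated correlation; Cbln1 -3.63, Slc17a7 -3.43).

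By limma 7512 of 12633 genes passed between orthotopic and GTML tumours, 3484 higher and 4028 lower in orthotopic tumours, and 2122 of them differed at least 2-fold. Gli1 was higher by 0.36 (limma adjusted p = 0.0156) and Atoh1 by 0.52 (limma adjusted p = 0.0263). They turned to -0.080 (0.592) and -0.23 (0.0527) without the E16C tumours, where the SHH list was lost as well (0.197). The Atoh1 call was also lost with quantile normalization (0.06). Without the P0F tumours Ifit1 differed by 0.41 (0.188), Oasl2 by 0.22 (0.28) and Gfap by 1.16 (0.0623), and the interferon (0.769) and forebrain (0.0976) lists were lost. The mature granule list was lost without any 1 of the 3 groups (0.0949, 0.0624 and 0.06) and when arrays were centred on their medians (0.0591). Without the 4 GTML arrays of replicates 20, 22, 30 and 31, a setting chosen after seeing the data, 8747 genes passed, Mki67 was higher by 0.49 (limma adjusted p = 0.00011), astrocyte genes passed as higher (adjusted p = 0.0353) and the forebrain list was lost (0.0785).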

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

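The tests on genes that the GTML tumour cells lack and on a single share of their RNA, the values of P0F GFP NSCs for interferon genes, all tests on the 4 GTML tumour arrays and the comparison with the spread for immune cells in P0F tumours were chosen only after the result was seen. Among 84 measures of the 5 P7 cerebella, 5 had a sample far from the others, where chance gives about 1 in 20. Gnb3 was 6.87 in replicate 3, against 6.66 to 6.70 in the others. Cd8a was 5.33 in replicate 1 and Notch1 9.29 in replicate 2. The mature granule neuron score was 9.80 and the Purkinje score 10.78 in replicate 1. The test of whether the tumour against GFP NSC difference depends on origin passed in 377 genes, among them Olig2 (adjusted limma p = 0.00589) and Otx2 (adjusted limma p = 0.00305). It rests on a single GFP array each for E16C and P0F, the latter an array that stands apart (below), and 37, 19 or 1 passed without the sorted P0C, the unsorted P0C or the forebrain arrays. The GTML tumour cells, an array used in no comparison, had a photoreceptor score of 7.53, above the highest of the P7 cerebella (6.33).

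Other splits of the same arrays gave fewer genes than the real split in each comparison examined. For GTML tumours against P7 cerebella 1 of 100 splits, the real one, gave 7082 genes, and the highest other gave 4274. The real split also gave the most genes for tumours against GFP NSCs (1408, highest other 67) and tumour cells against tumours (450, highest other 65). It did so for orthotopic against GTML tumours as well (7512, highest other 462), where the labelling protocol goes with the split. With 100 splits a share smaller than 1 in 100 cannot be shown, and these counts do not tell why the groups differ. For the comparisons of 3 tumours with 3 the 10 splits are too few for a share under 0.05, with 84 genes against a highest other of 3 for P0C and E16C, 141 against 0 for P0F and P0C, and 33 against 0 for P0F and E16C by limma, all at adjusted p 0.05.

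The P0F GFP NSC array held genes of GTML tumours, such as Crx at 10.19 and Otx2 at 11.82. Of 41 genes at least 3 log2 units higher in the GTML tumour cells than in 8 other cultures, 82.9% lay above all 8 in this array, against 4.49% of all genes, which is consistent with RNA of GTML-derived cells of some kind in the sample. RNA of the GTML-derived culture that was measured, at a single share, is argued against by the spread of the share these genes imply (median 31.5%, from -2.07% to 125%): 7 of them, among them Igf2bp1, Igf2, Bmp5 and Myl1, lay at least 2 log2 units below the level that the median share would give. In the P0F tumour cells, of the same forebrain origin, 2.56% of the genes lay above the 5 cerebellar cultures. These cells were among the 8 cultures in which the genes had to be low, which removes genes that forebrain origin raised there. The value therefore cannot decide on forebrain origin as the source. A full exchange for GTML-derived cells is argued against by the 18 genes those cells lack, of which 100% lay at least 1 log2 unit above them in the array. The planned test on forebrain genes, with a median difference of 0.020, was void, since these genes do not separate P0F from GTML tumour cells. RNA of other GTML-derived material, such as the GTML tumours, was not tested as a source here. It stays open, as do forebrain origin and a state of the culture itself.

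In 4 GTML tumour arrays the photoreceptor score lay below the other 28. For replicates 20 and 30, 5 of 5 lists of mature brain cells scored above all 28, which is consistent with neighbouring brain tissue in the dissected sample. For replicate 31 (0 of 5) the same test argues against neighbouring brain tissue. For replicate 22 (1 of 5, the Purkinje score at 8.07) the test argues against it less firmly. Its general neuronal and mature granule neuron scores, both 8.03, lay below the 28, but a compressed signal would itself lower high scores. The values of replicate 22 had an SD of 1.91, below the lowest of the other 31 (2.01), so compressed signal of a poor array may account for part of it, while its fibroblast (10.00) and endothelial (9.59) scores lay above the 28. For replicate 31 no explanation was tested that the values bear out, and a tumour of another kind stays open as untested.

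Interferon genes were higher in P0F than in P0C tumours by a median of 2.69 (SD 1.21 over 9 genes). More immune cells could raise them. Microglia and macrophage genes differed by 0.50 (SD 0.34 over 12 genes) and lymphocyte genes by 0.44. The bounds set in advance (under 0.5 against, at least 1 for) left 0.502 undecided. Between P0F and E16C tumours the median differences were 2.74 for interferon genes and 0.72 for microglia and macrophage genes. The later comparison with the spread shows that microglia genes rose less than interferon genes. It cannot decide whether immune cells were the source, since these genes need not rise in step. An interferon state already present in the cultures could raise them too. The interferon genes lay at -0.52 (SD 0.39) in P0F tumour cells relative to E16C and P0C tumour cells. That is partly a high level in E16C tumour cells (score 8.33). In P0F GFP NSCs, the array that stood apart above, they lay at -0.83 (SD 0.91) relative to the other GFP NSCs. Of those, the P0C arrays scored high (8.31 and 8.56, E16C 7.68). The P0F cultures themselves scored 7.12 and 7.12, against 8.99 to 10.52 in P0F tumours. So neither P0F culture measured held the level of the tumours. These cultures cannot decide whether the state was present before transplantation. The tumour cells were grown out of a tumour, and the GFP NSCs were controls. A response of the host to the transplant, an effect of forebrain origin and the state of forebrain N-myc NSCs, which were not analysed here, stay open, as untested.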

How the results depend on the processing

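The settings with filled blanks, without the 4 GTML tumours, without both P0C GFP NSC arrays, without the forebrain arrays without the 3 orthotopic tumours numbered 1 and with 5 GTML tumours of the same numbers as the cerebella but no block were chosen only after the result was seen; the others were planned. Over all settings 3319 list results kept their direction and side of the threshold, 142 became weaker and 93 stronger, and for named genes these counts were 3202, 288 and 23, with 2 reversed. Of the values that answer a comparison, 152 kept theirs or stayed within 1.5 times the count, 54 moved, 5 became weaker and 3 reversed. The reversed genes were Gli1 (-0.080) and Atoh1 (-0.23) in orthotopic against GTML tumours without the E16C tumour group. Counting only changes of at least 2-fold gave 1845 genes for GTML tumours against P7 cerebella, 607 for tumours against GFP NSCs, 277 for tumour cells and 2122 for orthotopic against GTML tumours, a smaller number by construction. With all 56 arrays in a single model the counts were 989 (P0C against E16C), 1329 (P0F against P0C), 599 (P0F against E16C), 2571 (tumours against GFP NSCs), 432 (N-myc against GFP NSCs), 1706 (tumour cells) and 1711 (origin). Array weights gave 674 (P0F against P0C), 64 (P0F against E16C), 4557 (GFP NSCs), 1388 (N-myc), 1685 (tumour cells) and 2295 (origin). Replicate numbers as a block gave 36, 25 and 0 by limma for the 3 comparisons between origins (1375 unadjusted for the last). Arrays of the same number were not plainly more alike than others, but 3 such pairs for each comparison are too few to exclude a pairing. With only the compared groups in the fit the counts were 8 (P0C against E16C) and 238 (P0F against P0C). Other counts were 297 for tumour cells with quantile normalization, 4 for N-myc NSCs with filled blanks, 333 for tumours against GFP NSCs without both P0C GFP arrays and 1 for origin without forebrain. Leaving out single replicates gave 35 to 230 genes for P0C against E16C, 0 to 251 for P0F against P0C (0 by limma with 1350 unadjusted), 0 to 20 for P0F against E16C (0 by limma with 1121 and 1374 unadjusted), 563 to 1542 for GFP NSCs, 0 to 10 for N-myc NSCs (0 by limma with 285, 521, 567 and 1748 unadjusted), 129 to 324 for tumour cells, 19 to 37 for origin and 6272 to 6515 for GTML tumours. The likeness to GTML tumours of cerebellar minus forebrain tumours ran from -0.0303 to 0.0945. Differences in SHH score ran from -1.14 to -0.478, -0.389 to -0.14 and -1.42 to -0.763. Across all 32 GTML tumours, as planned, the SHH score had r = -0.821 with the photoreceptor, 0.788 with the WNT, -0.767 with the cell cycle, -0.734 with the Myc-induced and 0.431 with the astrocyte score. Without the 4 tumours these were -0.322, 0.36, 0.531, 0.491 and -0.129, so 3 of the signs turned, and without the 2 tumours farthest from the median the last 3 were -0.291, -0.309 and 0.203. Apart from the change to at least 2-fold, the cause was not tested. The size of differences against levels under 6.30 is less certain than that of others.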

Other observations

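The genes and arrays below were chosen after their values were seen, and nothing here was tested. GTML replicate 31 was a cycling tumour (cell cycle score 10.57, Mki67 10.16) without photoreceptor genes, with Crx at 6.64, Otx2 at 6.18 and Impg2 at 5.86. Its Mycn level was 6.61. It held the hyaluronan receptor Cd44 at 10.80, Eya1 at 12.18, Olig2 at 9.42, Nkd1 at 9.61 and the interferon-induced Rsad2 at 8.27, and low levels of Pax6 (4.70), Prom1 (5.10), Slc1a3 (5.66) and Fabp7 (4.86). Of 267 list genes measured in all 32 GTML tumours, 5 lay above and 9 below all other 31 tumours by at least 1 log2 unit in this array, against 18 and 5 in replicate 22 and 4 and 4 in replicate 20.

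Prm1, a protamine of sperm chromatin, was high in the 9 orthotopic tumours, at 11.85 ± 1.15 (SD, n = 3) in E16C, 11.02 ± 1.94 in P0C and 10.28 ± 0.77 in P0F tumours. It was low in the tumour cells (7.37, 7.10 and 7.27), in GTML tumours (6.81 ± 0.15) and in P7 cerebella (6.66), and stood at 10.03 in P0C N-myc NSCs, 9.95 in P0F GFP NSCs, 8.13 in E16C N-myc NSCs, 8.38 and 8.03 in sorted and unsorted P0C GFP NSCs and 7.41 in E16C GFP NSCs. The interferon score was 8.33 in E16C tumour cells and 8.31 and 8.56 in P0C GFP NSCs, against 7.08 to 7.68 in the other cultures. The GTML tumour cells had a cell cycle score of 11.21 and a Myc-induced score of 10.92, and the SHH score of the E16C tumour cells was 9.21.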
